A study of Mus musculus with 15 samples.

How the data were processed

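The data are 15 Illumina mouse bead arrays, each hybridised with biotin-labelled cRNA in 1 colour. The cells were peritoneal macrophages that thioglycollate, an irritant broth, had drawn into the abdominal cavity of mice. Per the labels' protocols, the adherent cells were kept in medium with 0.5% serum and 5.5 mM glucose, and control or fatty acid-loaded cells received LPS at 10 ng/ml or vehicle for 24 h before RNA extraction. The fatty acid and the loading procedure are not given in the sources used here. The labels place 3 arrays in the unstimulated group and 4 each in the groups with fatty acid (FA), LPS, or both (FA+LPS). They also number the arrays by experiment, and the series' design text calls these 4 experiments independent. The spread within a group is therefore one between experiments. The main fit, with group as its only term, ignores that arrays of different groups share an experiment. Experiment 2 has no unstimulated array here.

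The authors deposited a table of log2 signals for 45281 probes that was not normalized between arrays, and it holds no detection p-values. The base of the logarithm follows from the values: 97.6% of the back-transformed signals are numbers of 5 decimals within 0.05 of a unit of the last decimal. The authors' value table holds log2 values for 25784 of these probes. It equals a quantile normalization of the deposited log2 signals over those probes to within 0.000949, and the median of every column is 6.03. The software, any background treatment before deposit and the rule by which the authors retained those probes are not given in the sources used here.

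Groups, comparisons, tests, 28 gene lists (6 of them markers of other cell types), the rule for named genes and most alternatives were fixed before the data were examined. That plan expected detection p-values. As none are in the table, the fallback written in the plan was used: normexp background correction with an offset of 50, without control probes, then quantile normalization over all probes. An alternative of that plan thereby became the procedure itself and was not run separately. In place of detection p-values, a probe counted as above background where its signal exceeded the 95th percentile of the 19497 probes that the authors did not retain on that array, a rule chosen after the tables were seen. Retained probes were tested where this held on at least 3 arrays, which 24195 did.

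Probes were named from the platform annotation. Of the retained probes, 21476 carried 1 gene symbol, 10 carried several and 4298 were unnamed, and no symbol needed an update through its Entrez identifier. The brightest probe above background, by its mean over all arrays, stood for a gene, which left 12984 genes, 4827 of them with several such probes. No other probe of a named gene was called in the opposite direction in the 140 pairs of a gene and a comparison that had another probe, but in 45 of the 100 such pairs that were called, another probe was not called.

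Linear models were fitted with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes) to all 15 arrays with group as the only term. The fit had 11 residual and 3.20 prior degrees of freedom. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg's method over the genes of a comparison, and a gene was called below an adjusted p of 0.05. The 6 comparisons were each treatment against unstimulated cells, FA+LPS against FA and against LPS, and the interaction, which is the fatty acid effect with LPS minus that without it. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Lists with fewer than 5 measured members were only counted. Where a group had no array above background for a gene, the fold is given as a lower bound against the background level of those arrays.

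The text names, per comparison, the 8 genes that rose most and the 8 that fell most (5 each for FA+LPS against LPS, FA+LPS against unstimulated cells and the interaction) among called genes whose groups did not overlap. It also draws on up to 4 called members of each list and on a fixed set of lipid and inflammation genes. Some genes of that set are not reported here.

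The number of arrays limits the precision. The 95th percentile of the log2 signal lay between 8.53 and 9.57 on 14 arrays and at 7.77 on FA replicate 1, where 16756 probes were above background against 18945 to 19973 elsewhere. No arrays of a group were copies: the closest pair correlated at 0.990 with a median absolute log2 difference of 0.0943. The fit was tested on simulated data with 12984 genes. For FA+LPS against LPS it recovered 74.6% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold, with 6.31% false calls. For FA against unstimulated cells these shares were 61.2%, 88.1% and 100%, with 2.76% false calls. The simulated values were drawn independently for each array and gene, without the deviations that arrays of an experiment share. These shares may therefore not hold for the real arrays.

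Experiment numbers mark shared independent experiments, so they pair the arrays. Deviations from the group means correlated between arrays of the same experiment at a median of 0.222 (0.0438 to 0.805 over 21 pairs, 17 of them above 0.1) and between arrays of different experiments at a median of -0.0745 over 63 pairs. The alternative fit with a replicate block called 344 genes for FA+LPS against LPS, where the main fit, which ignores the pairing, called 89. The arrays lay on 3 slides. Slide 1 held experiment 1 and FA replicate 4, slide 2 held experiment 2 with the LPS and FA+LPS arrays of experiment 4, and slide 3 held experiment 3 with unstimulated replicate 4. Slide was also used as a block, and differences were taken within slides.

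The other alternatives were a random replicate block, both blocks together, no background correction, median scaling in place of quantile normalization, the authors' value table, no filter or a stricter filter on dim probes (above the 99th percentile on every array of a group), the mean of a gene's probes, every probe tested, trend and robust moderation, array weights, only the groups compared, omission of experiment 2 or of each array, a 2-fold threshold, and fry in place of camera. A background correction with the unretained probes as negative controls (offset 16) and a replicate block with an estimated correlation were added after the data were seen.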

Results

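Gene expression was measured on 15 arrays of cultured mouse peritoneal macrophages, phagocytes recruited to the abdominal cavity by an irritant. Unstimulated cells gave 3 arrays. Cells loaded with fatty acid (FA), cells given 10 ng/ml bacterial lipopolysaccharide for 24 h (LPS, an agonist of Toll-like receptor 4) and cells given both (FA+LPS) gave 4 arrays each, from 4 independent experiments. The series' title places the work in a study of how Toll-like receptor agonists prolong triglyceride retention in macrophages. Values are log2 differences ± SE from limma with adjusted p-values, and higher and lower refer to the treated group. The leading principal component held 71.3% of the variance and parted the 8 arrays with LPS from the 7 without it.

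LPS alone, compared with unstimulated cells, changed the cells most visibly in their inflammatory genes. Il1b, which encodes the cytokine interleukin-1 beta, rose by 7.84 ± 0.10 (229-fold, adjusted p = 5.54e-16, 4 arrays against 3). It was followed by the formyl peptide receptor Fpr2 (6.76 ± 0.32), the neutrophil chemoattractant Cxcl1 (6.49 ± 0.41), the chemokine Ccl5 (6.44 ± 0.13), the non-classical MHC gene H2-M2 (6.43 ± 0.19), the interferon-induced gene Ifit3 (6.16 ± 0.46), the activin subunit gene Inhba (6.03 ± 0.14) and the monocyte chemoattractant Ccl7 (5.86 ± 0.49). Of 33 measured NF-kB-responsive cytokines and mediators, 30 rose and none fell (32 adjusted over the list alone; list adjusted p = 4.13e-39). Tnf rose by 4.77 ± 0.21 and Acod1, whose enzyme makes itaconate, by 5.06 ± 0.20. Nos2, which encodes inducible nitric oxide synthase, did not pass the test (0.72 ± 0.25, adjusted p = 0.0571). It passed with a replicate block (0.83, adjusted p = 0.00697), without LPS replicate 2 (adjusted p = 0.00533) and without FA+LPS replicate 4 (adjusted p = 0.0493). Of 37 interferon-responsive genes, 33 rose and 1, Irf8 (-0.69 ± 0.16), fell (list adjusted p = 1.30e-28, and adjusted p = 0.0605 with an estimated correlation). Isg15 rose by 5.73 ± 0.38 and Gbp2 by 4.62 ± 0.21. Of 24 genes of the TLR pathway and its negative regulators, 12 rose and 1 fell (list adjusted p = 6.13e-06, and adjusted p = 0.0573 with an estimated correlation). They included Tlr2 (3.30 ± 0.13), Socs3 (4.55 ± 0.32), which restrains cytokine signalling, the inhibitory kinase Irak3 (2.11 ± 0.17) and Aoah (1.79 ± 0.19), whose enzyme deacylates LPS. Tlr4 measured 0.09 ± 0.15 (adjusted p = 0.790), while 1 of its 2 other probes passed (0.01 and 0.36).

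The genes that fell most with LPS were the cell cycle inhibitor Cdkn1c (-4.86 ± 0.26, 29.0-fold, adjusted p = 6.26e-09), the surface receptor Cd93 (-4.08 ± 0.20), the sorting receptor Sort1 (-3.46 ± 0.42), the metalloproteinase inhibitor Timp2 (-3.40 ± 0.24), the diacylglycerol lipase Daglb (-3.10 ± 0.13), the lysosomal transporter Slc46a3 (-3.07 ± 0.13), the kinase Matk (-3.06 ± 0.14) and the sialyltransferase St6gal1 (-3.06 ± 0.13). The 3 other probes of Sort1 measured from -3.00 to -0.17, and 2 of them were not called. Triglyceride lipolysis genes were among the lower lists: 5 of 8 measured members fell and none rose (6 adjusted over the list alone; list adjusted p = 0.00169, and adjusted p = 0.0410 with an estimated correlation). Besides Daglb, these were the lysosomal acid lipase Lipa (-2.29 ± 0.43), the monoglyceride lipase Mgll (-2.14 ± 0.17), Abhd5 (-0.83 ± 0.12), the coactivator of adipose triglyceride lipase, and that lipase itself, Pnpla2 (-0.69 ± 0.19, adjusted p = 0.0163, or 0.0919 without unstimulated replicate 4). Hormone-sensitive lipase, Lipe, measured 0.13 ± 0.06 (adjusted p = 0.177). Of 10 lipid droplet coat and assembly genes, 1 rose and 3 fell, and the list was not called (adjusted p = 0.437). The droplet coat gene Plin2 fell by 1.59 ± 0.25 and the seipin gene Bscl2 by 0.92 ± 0.09.

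Fatty acid uptake and esterification genes had members in both directions with LPS, while called oxidation genes were lower. Of 10 fatty acid uptake and binding genes, 2 rose and 4 fell. Of these, Fabp3 (1.86 ± 0.21) and the caveola gene Cav1 (1.46 ± 0.21) were higher and Fabp5 (-2.03 ± 0.21) and the scavenger receptor Cd36 (-1.02 ± 0.11) lower, and the list was not called (adjusted p = 0.518). The other probe of Fabp5 measured -0.03 and was not called. Of 17 acyl-CoA synthesis and glycerolipid esterification genes, 1 rose and 3 fell (list adjusted p = 0.736). The acyl-CoA synthetase Acsl5 rose by 0.69 ± 0.14, and the phosphatidate phosphatase Lpin1 fell by 1.75 ± 0.11. Dgat1, for the last step of triglyceride synthesis, measured -0.02 ± 0.10 (adjusted p = 0.942). Of 26 fatty acid oxidation genes, 9 fell and none rose (11 adjusted over the list alone; list adjusted p = 0.000885, and adjusted p = 0.0616 with an estimated correlation). They included the peroxisomal enzyme Hsd17b4 (-1.46 ± 0.07) and the electron transfer flavoprotein subunit Etfb (-1.13 ± 0.19). Sterol synthesis and uptake genes had 9 of 18 lower and none higher (10 adjusted over the list alone; list adjusted p = 0.000745, and adjusted p = 0.303 with an estimated correlation), with Cyp51 at -1.18 ± 0.30. Fatty acid synthesis and desaturation genes had 8 of 15 lower and none higher (9 adjusted over the list alone; list adjusted p = 0.00155, and adjusted p = 0.246 with an estimated correlation). These included the desaturases Scd1 (-1.86 ± 0.14) and Fads1 (-1.35 ± 0.22). Pparg, the lipid-sensing nuclear receptor, fell by 3.03 ± 0.20 while Ppard rose by 1.10 ± 0.16. The 2 other probes of Pparg measured -0.74 and 0.20, and 1 of them was not called. The other probe of Ppard measured -0.005 and was not called. The PPAR-responsive list (1 of 20 higher, 6 lower, adjusted p = 0.0659) and the LXR-responsive and sterol efflux list (1 of 14 higher, 4 lower, adjusted p = 0.0799) were not called.

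Other groups of genes also moved with LPS. Of 19 genes of the unfolded protein and integrated stress response, 8 rose and none fell (9 adjusted over the list alone; list adjusted p = 0.000169, and adjusted p = 0.0208 with an estimated correlation), including the chaperone Pdia4 (1.30 ± 0.17) and the phosphatase subunit Ppp1r15a (1.12 ± 0.13). Glycolysis and HIF-responsive genes had 9 of 20 higher and 2 lower (list adjusted p = 0.00121, and adjusted p = 0.0605 with an estimated correlation), with the glucose transporter Slc2a1 at 1.09 ± 0.22. NRF2-responsive genes had 5 of 15 higher and 2 lower (list adjusted p = 0.0169, and adjusted p = 0.303 with an estimated correlation), led by the cystine transporter Slc7a11 (2.09 ± 0.28). Lysosomal enzymes and membrane proteins had 11 of 21 lower and 1 higher (list adjusted p = 0.000858, and adjusted p = 0.0605 with an estimated correlation), with the glucuronidase Gusb at -1.35 ± 0.12. Tricarboxylic acid cycle genes had 7 of 18 lower and none higher (list adjusted p = 0.0277, and adjusted p = 0.246 with an estimated correlation), with Idh1 at -2.36 ± 0.22. That call was lost without LPS replicate 3 (adjusted p = 0.0819) and without unstimulated replicate 3 (adjusted p = 0.0533). MHC class II and costimulation genes had 4 of 11 higher and 1 lower, with Cd40 at 3.52 ± 0.26 (list adjusted p = 0.0411, and adjusted p = 0.269 with an estimated correlation). The shift was not held with slide as a block (adjusted p = 0.0786). Its median had opposite signs within slide 1 (0.35) and slide 3 (-0.14). It was also lost without LPS replicate 1 (0.0524), LPS replicate 2 (0.0742), unstimulated replicate 1 (0.0581) or unstimulated replicate 4 (0.140). The respiratory chain (5 of 31 lower, adjusted p = 0.315), the alternative activation markers (2 of 14 higher, 4 lower, adjusted p = 0.465) and the cell cycle list (2 of 22 higher, adjusted p = 0.430) were not called. Among the alternative activation markers, the mannose receptor Mrc1 fell by 2.86 ± 0.18 and Trem2 by 2.73 ± 0.17.

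Markers of cell types were counted as well. Macrophage markers went both ways (5 of 12 higher, 4 lower, list adjusted p = 0.280), with Cd14 at 1.88 ± 0.26 and Tyrobp at -1.69 ± 0.26. Neutrophil markers had 3 of 8 higher and 1 lower (list adjusted p = 0.323), with S100a8 at 1.09 ± 0.22 and Ltf at -0.53 ± 0.12. Dendritic cell markers had 1 of 8 higher, Batf3 at 2.18 ± 0.28 (list adjusted p = 0.136), and mesothelial and fibroblast markers 1 of 10, Dcn at 2.26 ± 0.23 (list adjusted p = 0.732). B cell markers had 1 of 5 lower, Cd22 at -0.43 ± 0.10 (list adjusted p = 0.989). Of the lists too short for the set test, the T and NK cell markers had 1 of 2 lower, Il7r at -1.10 ± 0.27 (adjusted p = 0.00859, or 0.0522 without unstimulated replicate 1), and none of the 4 eosinophil and mast cell markers passed (median 0.04).

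In all, 2892 of 12984 genes changed with LPS alone, 1164 higher and 1728 lower, and 789 changed at least 2-fold. With slide as a block, 111 of 112 named genes past the threshold stayed past it. The median of the lipolysis list was -0.72 within slide 1 and -0.75 within slide 3, and that of the NF-kB list 2.00 and 2.37. With median scaling in place of quantile normalization, 927 genes were called, 60.0% of them higher against 40.2%, and 70 of the 112 named genes stayed past the threshold. Lipa (adjusted p = 0.0647), Plin2 (0.0935), Abhd5 (0.259), Bscl2 (0.40), Pnpla2 (0.696), Hsd17b4 (0.0586), Etfb (0.306), Cyp51 (0.292), Fads1 (0.153), Gusb (0.0830), Tyrobp (0.157), Cd22 (0.222), Il7r (0.293), Irf8 (0.318) and the tricarboxylic acid cycle list (0.264) did not.

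**Figure D1:**
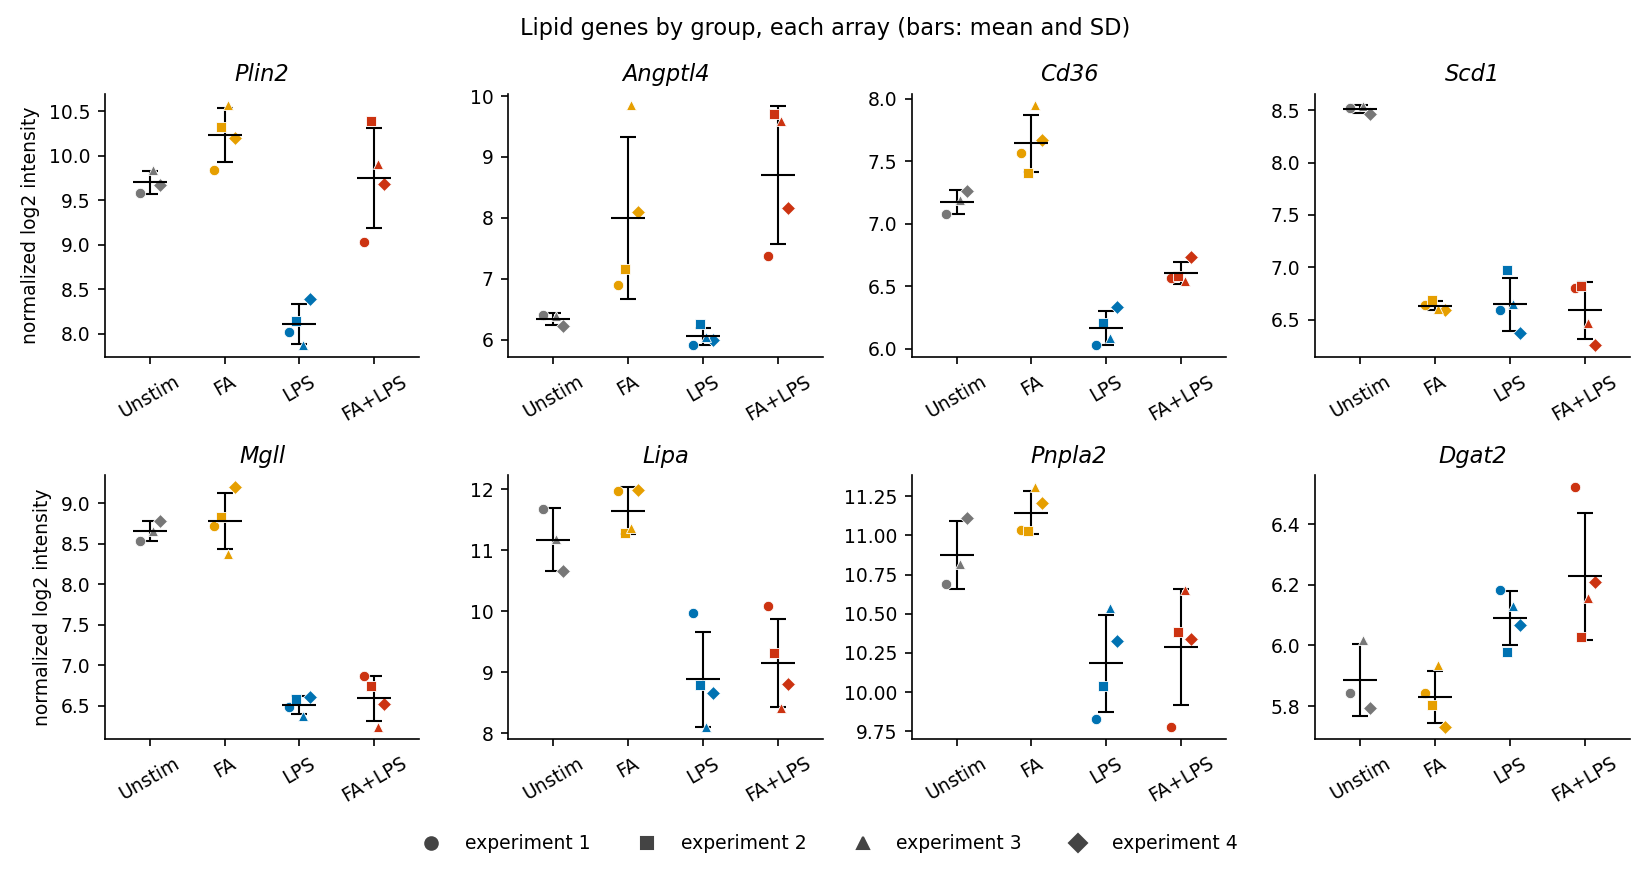
Normalized log2 signal of lipid-handling genes on each array, by group, with bars for mean and SD; n = 3 unstimulated arrays and 4 in each other group. Plin2 lay 1.59 lower with LPS than in unstimulated cells and 1.65 higher with FA+LPS than with LPS alone, whereas Mgll was lower in both groups with LPS.

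Fatty acid loading without LPS changed 1 gene by this test. Scd1, which encodes stearoyl-CoA desaturase, the enzyme that makes monounsaturated fatty acids, fell by 1.88 ± 0.14 (3.67-fold, adjusted p = 2.16e-05, 4 arrays against 3, no overlap). Other lipid genes did not pass: Angptl4, which encodes a lipoprotein lipase inhibitor, measured 1.67 ± 0.62, the droplet protein gene Hilpda 1.07 ± 0.33 and Plin2 0.53 ± 0.25 (each adjusted p = 1.00). Fatty acid oxidation genes were higher as a list although no member passed alone: 20 of 26 were higher, with a median of 0.11 (list adjusted p = 3.55e-06, and adjusted p = 0.0388 with an estimated correlation). The carnitine carrier Slc25a20 measured 0.47 ± 0.13 (adjusted p = 1.00). PPAR-responsive genes shifted up likewise, with 15 of 20 higher and 4 higher when adjusted over the list alone (list adjusted p = 3.55e-06, and adjusted p = 0.0388 with an estimated correlation). Fatty acid synthesis and desaturation genes shifted down, with Scd1 lower and 4 members lower when adjusted over the list alone (list adjusted p = 3.55e-06, and adjusted p = 0.203 with an estimated correlation). Neither the lipid droplet list (adjusted p = 0.0693) nor the lipolysis list (adjusted p = 0.220) was called.

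At an unadjusted p below 0.05, 374 genes differed, where chance alone gives 649. With a replicate block, 3 genes were called: Scd1, Acod1 (-0.94 ± 0.13, adjusted p = 0.0448) and the interferon-induced gene Ifi27l2a (lower, adjusted p = 0.0448). That block also called the sterol synthesis and uptake list lower (adjusted p = 0.00249, and adjusted p = 0.500 with an estimated correlation) and the LXR-responsive list lower (adjusted p = 0.0467, and adjusted p = 0.313 with an estimated correlation). With block and estimated correlation together, the oxidation and PPAR-responsive lists were not called (each adjusted p = 0.151). With slide as a block the lipid droplet list was called (adjusted p = 0.0497), although without the block it had adjusted p = 0.203 with an estimated correlation. The medians of the oxidation list within slides 1 and 3 were 0.12 and 0.23, those of the PPAR-responsive list 0.12 and 0.25 and those of the synthesis list -0.11 and -0.09. Leaving out FA replicate 4 added Ifitm6 (-0.88 ± 0.12, adjusted p = 0.0394) and leaving out unstimulated replicate 3 added Mfng (-0.56 ± 0.08, adjusted p = 0.0329). With median scaling the oxidation list was not called (adjusted p = 0.0669). Ifi27l2a, Ifitm6 and Mfng were chosen for mention after their values were seen.

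LPS given to loaded cells, compared with loaded cells without it, gave a similar ranking of genes. Il1b rose by 8.03 ± 0.09 (262-fold, adjusted p = 1.32e-16, n = 4 in each group), followed by Fpr2 (7.19 ± 0.30), H2-M2 (6.87 ± 0.18), Cxcl1 (6.59 ± 0.38), Ccl5 (6.26 ± 0.12), the chemokine Cxcl2 (6.13 ± 0.15), Acod1 (5.90 ± 0.19) and Inhba (5.83 ± 0.13). Cdkn1c fell by 5.06 ± 0.24 (33.3-fold), followed by Cd93 (-3.91 ± 0.18), St6gal1 (-3.10 ± 0.12), Daglb (-3.06 ± 0.12), Prr33 (-3.01 ± 0.13), Gask1b (-2.97 ± 0.09), Slc46a3 (-2.95 ± 0.12) and the adhesion receptor Adgre5 (-2.90 ± 0.17). The lipolysis list had 5 of 8 lower and none higher (list adjusted p = 0.000899, and adjusted p = 0.0330 with an estimated correlation), with Lipa at -2.49 ± 0.39, Mgll at -2.19 ± 0.16 and Pnpla2 at -0.86 ± 0.18. Plin2 did not pass the test (-0.48 ± 0.23, adjusted p = 0.183). It passed with slide as a block (-0.61, adjusted p = 0.0318) and without FA+LPS replicate 2 (adjusted p = 0.0268). Cd36 fell by 1.04 ± 0.10, Cav1 rose by 2.85 ± 0.19, and Dgat2, which encodes a triglyceride-forming acyltransferase, rose at least 1.14-fold (adjusted p = 0.00644). Hilpda measured 0.72 ± 0.31 (adjusted p = 0.126) and rose with a replicate block (0.72, adjusted p = 0.0389), without FA replicate 3 (adjusted p = 0.0188) or without FA+LPS replicate 1 (adjusted p = 0.0486).

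NF-kB-responsive genes had 27 of 33 higher (list adjusted p = 1.27e-38, and adjusted p = 0.00192 with an estimated correlation). Interferon-responsive genes had 29 of 37 higher and 1 lower (list adjusted p = 9.97e-26, and adjusted p = 0.0914 with an estimated correlation), and TLR pathway genes had 10 of 24 higher and 1 lower (list adjusted p = 8.25e-07, and adjusted p = 0.0430 with an estimated correlation). Glycolysis and HIF-responsive genes had 9 of 20 higher (list adjusted p = 0.000179, and adjusted p = 0.0430 with an estimated correlation). NRF2-responsive genes had 5 of 15 higher and 2 lower (list adjusted p = 0.0149, and adjusted p = 0.445 with an estimated correlation), a call lost without FA+LPS replicate 2 (adjusted p = 0.126). Lysosomal genes had 11 of 21 lower and 2 higher with a mean of -0.42, but the mean was 0.03 with median scaling (list adjusted p = 0.00269, and adjusted p = 0.0963 with an estimated correlation). Neutrophil marker S100a8 rose by 2.16 ± 0.20, while its list was not called (2 of 8 higher, 1 lower, adjusted p = 0.101). Of other markers, 5 of 12 were higher and 3 lower for macrophages (adjusted p = 0.166), and 1 was higher for dendritic cells and for fibroblasts and 1 lower for B cells and for T cells. In all, 2567 genes changed, 1089 higher and 1478 lower, 655 of them at least 2-fold. With slide as a block all 57 named genes past the threshold stayed past it, and the median of the lipolysis list within the 3 slides was -0.80, -0.64 and -0.54. With median scaling, 925 genes were called, 75.0% of them higher against 42.4%. Then Lipa (adjusted p = 0.0537), Pnpla2 (0.723) and Bscl2, which measured -0.40 ± 0.08 before and 0.21 after, lost their call.

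The LPS effects in unloaded and in loaded cells come from separate arrays but from the same experiments. LPS and FA+LPS arrays of an experiment deviated from their group means alike (correlation 0.560 to 0.805), which the expected overlap does not take into account. Of the called genes, 813 were higher in both comparisons (97.6 expected of independent lists) and 1247 were lower in both (197 expected), while 1 gene was called in opposite directions. Across genes, which are not independent replicates, the log2 differences correlated at 0.94 (Pearson) and 0.76 (Spearman). The slope of the response of loaded cells on that of unloaded cells, over genes called with LPS in unloaded cells, was 0.887. Those genes were chosen by their calls in unloaded cells, so the slope does not show a weaker response in loaded cells. With median scaling 637 genes were shared in direction against 2060.

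**Figure D2:**
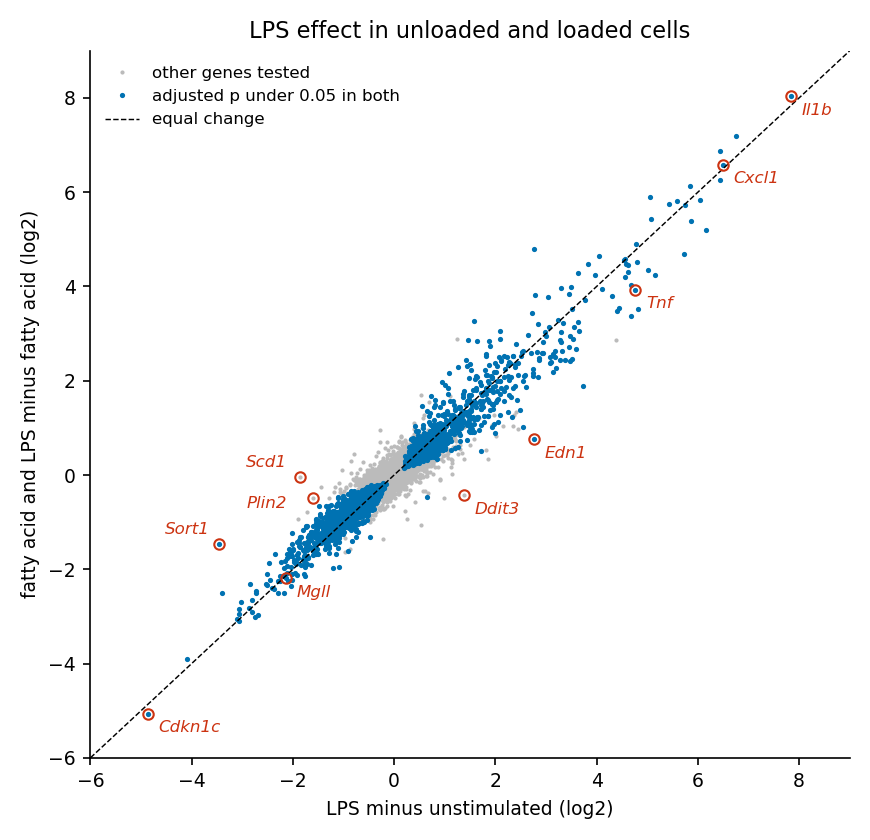
Log2 difference with LPS in fatty acid-loaded cells (vertical axis) against that in unloaded cells (horizontal axis), each point a tested gene. Il1b lies at 7.84 and 8.03, Mgll at -2.14 and -2.19, and the Pearson correlation across genes is 0.94.

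Fatty acid-loaded cells given LPS, compared with cells given LPS alone, differed in single genes of lipid handling and the stress response and in several of the fixed lists. Sort1 rose by 2.51 ± 0.39 (5.71-fold, adjusted p = 0.00657, n = 4 in each group), Plin2 by 1.65 ± 0.23 (3.13-fold, adjusted p = 0.00313), Cav1 by 1.41 ± 0.19, the mannosidase Man2a1 by 1.31 ± 0.22 and the platelet factor gene Pf4 by 1.29 ± 0.20. The 3 other probes of Sort1 measured from 0.25 to 2.06, and 2 of them were not called. The vasoconstrictor gene Edn1 fell by 2.04 ± 0.23 (4.12-fold, adjusted p = 0.000612). It was followed by Ddit3, which encodes the stress transcription factor CHOP (-1.84 ± 0.35, adjusted p = 0.0226), the aquaglyceroporin Aqp9 (-1.74 ± 0.14), the pseudokinase Trib3 (-1.67 ± 0.22) and the nucleoside transporter Slc28a2 (-1.43 ± 0.22). Of 19 genes of the unfolded protein and integrated stress response, 5 fell and none rose (11 adjusted over the list alone; list adjusted p = 2.26e-12, and adjusted p = 0.000436 with an estimated correlation), including the asparagine synthetase Asns (-1.20 ± 0.18) and Ppp1r15a (-0.76 ± 0.12). Herpud1 (-0.62 ± 0.13, adjusted p = 0.0448) missed the threshold with any array but LPS replicate 4 left out (adjusted p from 0.0512 to 0.0953). Both Herpud1 and Ddit3 missed it without LPS replicate 1, LPS replicate 3 or FA+LPS replicate 1 (adjusted p of Ddit3 0.0617, 0.0503 and 0.0622).

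Fatty acid oxidation genes had 4 of 26 higher and none lower (11 adjusted over the list alone; list adjusted p = 2.26e-12, and adjusted p = 0.00237 with an estimated correlation), led by Etfb (1.09 ± 0.17), Slc25a20 (0.89 ± 0.12) and Hsd17b4 (0.60 ± 0.07). PPAR-responsive genes, 12 of which are also in other lists, had 2 of 20 higher, Plin2 and Slc25a20 (7 adjusted over the list alone; list adjusted p = 7.14e-06, and adjusted p = 0.0333 with an estimated correlation). Angptl4 had the largest difference of that list, 2.66 ± 0.57, and just missed the threshold (adjusted p = 0.0514). It passed with a replicate block (2.66, adjusted p = 0.0130) and with a slide block (adjusted p = 0.0246). Angptl4 also passed when FA replicate 1, FA replicate 3, FA+LPS replicate 1 or FA+LPS replicate 4 was left out (adjusted p from 0.0110 to 0.0444). Its other probe measured -0.04 and was not called. Hilpda (1.30 ± 0.31, adjusted p = 0.0725) and Cd36 (0.44 ± 0.10, adjusted p = 0.0725) also passed with the replicate block (adjusted p = 0.0131 and 0.0249). Single arrays mattered for these calls too: Hilpda passed without FA replicate 3 (0.0316) or FA+LPS replicate 1 (0.0415), and Cd36 without FA replicate 3 (0.0265). The FA arrays are in neither group compared here. Without FA replicate 3 the differences of Hilpda and Cd36 stayed at 1.30 and 0.44, and only the test changed. Lipid droplet genes had 2 of 10 higher, Plin2 and Bscl2 (0.57 ± 0.08; list adjusted p = 0.00771, and adjusted p = 0.0480 with an estimated correlation), a list call lost without LPS replicate 1 (adjusted p = 0.0888). Fatty acid uptake genes had 1 of 10 higher, Cav1 (list adjusted p = 0.000502, and adjusted p = 0.0264 with an estimated correlation). Sterol synthesis genes had 1 of 18 higher, Hsd17b7 (1.27 ± 0.20), and all 18 measured above 0 (9 adjusted over the list alone; list adjusted p = 6.15e-12, and adjusted p = 0.0727 with an estimated correlation). The other probe of Hsd17b7 measured 0.12 and was not called. Without any called member, the respiratory chain (27 of 31 higher, list adjusted p = 9.77e-06) and the tricarboxylic acid cycle (15 of 18 higher, list adjusted p = 7.23e-05) shifted up, each with adjusted p = 0.0480 with an estimated correlation.

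Among inflammatory genes, the interferon-responsive list had a mean of -0.62 and the NF-kB list -0.17. Of 37 interferon-responsive genes, 1 fell, the guanylate-binding protein gene Gbp5 (-1.09 ± 0.20, adjusted p = 0.0205), and 34 measured below 0 (10 lower adjusted over the list alone; list adjusted p = 8.59e-15, and adjusted p = 0.166 with an estimated correlation). The other probe of Gbp5 measured -0.20 and was not called. None of the 33 NF-kB-responsive genes passed. Their list had adjusted p = 0.00170, and adjusted p = 0.305 with an estimated correlation, a call lost without FA+LPS replicate 1 (adjusted p = 0.0630). Il1b measured 0.09 ± 0.09 (adjusted p = 0.923) and Tnf -0.63 ± 0.20 (adjusted p = 0.191). The lipolysis list did not shift (adjusted p = 0.360): Mgll measured 0.08 ± 0.16 and Pnpla2 0.10 ± 0.18. S100a8, a neutrophil marker, rose by 1.11 ± 0.20 (adjusted p = 0.0186), and the neutrophil list was not called (adjusted p = 0.319). With a replicate block the fatty acid synthesis, lysosomal and MHC class II lists were called too, each with adjusted p = 0.0487. With block and estimated correlation together they had adjusted p = 0.352, 0.103 and 0.419, and the calls of the uptake, lipid droplet, PPAR-responsive and tricarboxylic acid cycle lists (each 0.0753) and of the respiratory chain (0.0901) were lost.

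In all, 89 genes differed between FA+LPS and LPS, 49 higher and 40 lower, 25 of them at least 2-fold. Of all genes, 1271 had an unadjusted p below 0.05, where chance gives 649. A replicate block called 344 genes, all 89 included, and a slide block 166. The slide block kept the calls of all 30 named genes. LPS and FA+LPS arrays of an experiment shared a slide, so differences between slides cancel here. The list medians within the slides were -0.54, -0.29 and -0.38 for the stress response list, 0.21, 0.25 and 0.23 for fatty acid oxidation, and -0.60, -0.68 and -0.40 for interferon-responsive genes. The count was 6 with median scaling (2 higher and 4 lower, 33.3% higher against 55.1%), where Edn1, Aqp9, Slc28a2 and Cav1 were the named genes still called, 12 when only these 8 arrays were fitted, and 32 without experiment 2. It was 57 without FA+LPS replicate 2 and 186 without FA+LPS replicate 4. Of the 30 named genes, 5 stayed called when only these 8 arrays were fitted and 15 without experiment 2. Ddit3 missed the threshold without LPS replicate 1, 3 or 4 or FA+LPS replicate 1 (adjusted p from 0.0503 to 0.0772). Gbp5 and S100a8 missed it without any of LPS replicate 4 or FA+LPS replicates 1, 2 and 3 (0.0530 to 0.0727). Gbp5 also missed it without LPS replicate 3 (0.0503) and S100a8 without LPS replicate 1 (0.0543).

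**Figure D3:**
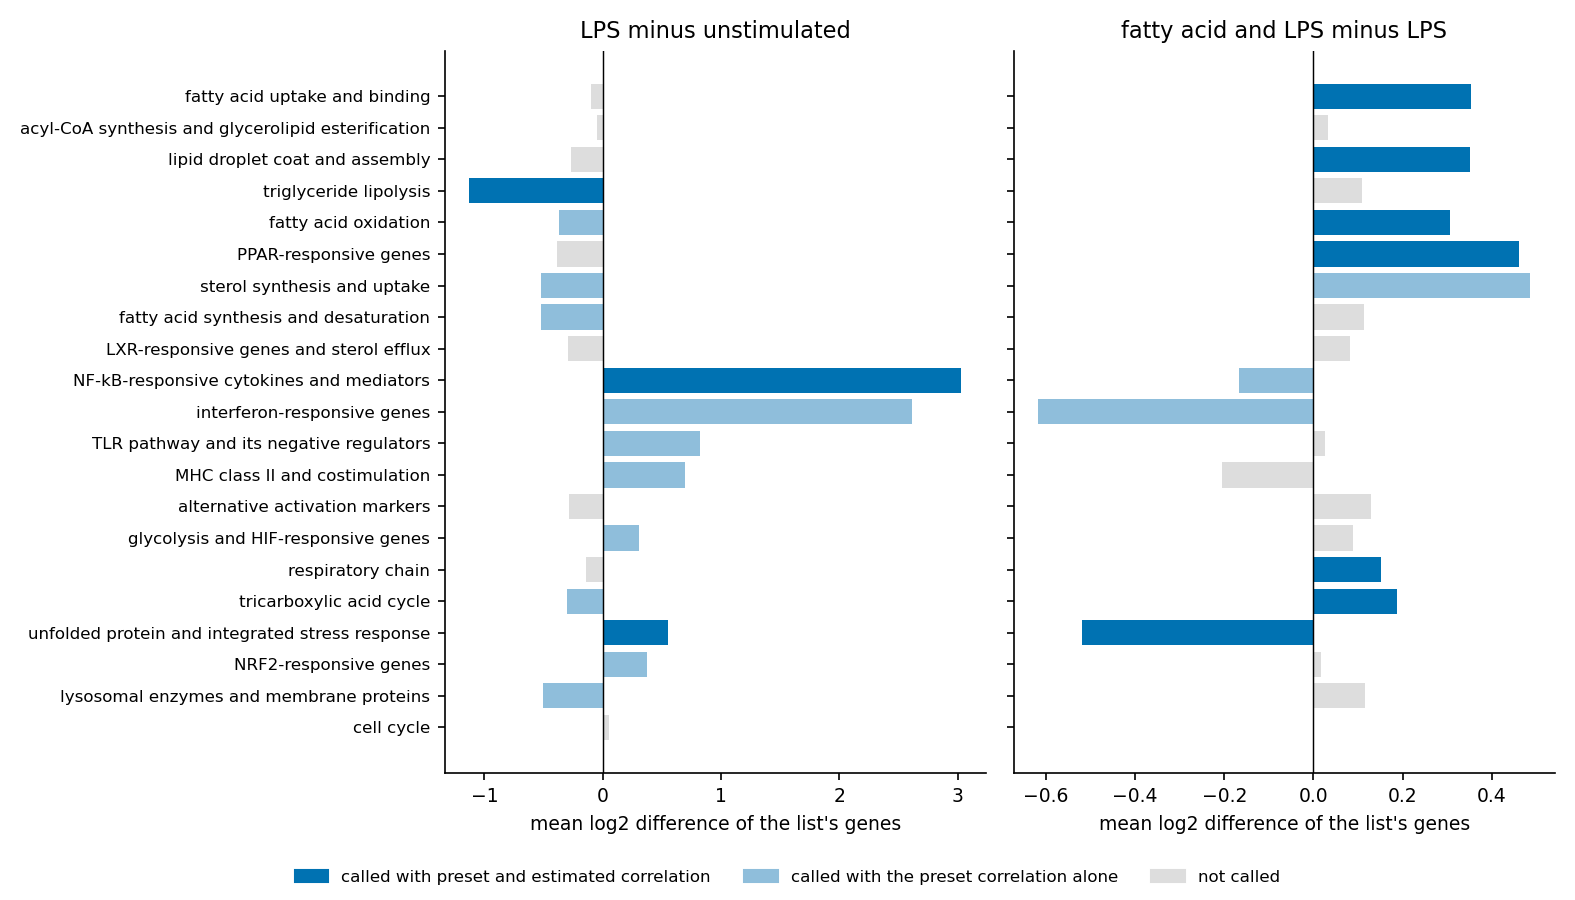
Mean log2 difference of the members of each gene list for LPS against unstimulated cells (left; 4 arrays against 3) and for FA+LPS against LPS (right; 4 arrays each), colored by the list test. The unfolded protein and integrated stress response list lies at 0.55 with LPS alone and at -0.52 for FA+LPS against LPS, and the lipolysis list at -1.13 and 0.11.

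Cells given both fatty acid and LPS, compared with unstimulated cells, kept the inflammatory changes of LPS alone at the top of the ranking. Il1b rose by 7.94 ± 0.10 (245-fold, adjusted p = 4.68e-16, 4 arrays against 3), then Fpr2 (7.19 ± 0.32), H2-M2 (6.80 ± 0.19), Cxcl1 (6.60 ± 0.41) and Ccl5 (6.17 ± 0.13). Cdkn1c fell by 5.41 ± 0.26, then Cd93 (-3.63 ± 0.20), Adgre5 (-3.44 ± 0.19), St6gal1 (-3.24 ± 0.13) and Prr33 (-3.22 ± 0.14). Lipolysis genes had 5 of 8 lower and none higher (list adjusted p = 0.00303, and adjusted p = 0.0575 with an estimated correlation), with Mgll at -2.06 ± 0.17 and Lipa at -2.02 ± 0.43. Hilpda rose by 1.79 ± 0.33 (3.46-fold, adjusted p = 0.00114) and Angptl4 by 2.37 ± 0.62 (adjusted p = 0.0134, or 0.0515 without unstimulated replicate 4 and 0.0552 without experiment 2), whereas Plin2 measured 0.05 ± 0.25 (adjusted p = 0.941). The other probe of Angptl4 measured 0.09 and was not called. Among oxidation genes, whose list was not called (4 of 26 higher, 5 lower, adjusted p = 0.750), Acaa1a rose by 0.68 ± 0.13 and Slc25a20 by 0.64 ± 0.13. Scd1 fell by 1.92 ± 0.14 and the synthesis list by a mean of 0.41 (3 of 15 lower; list adjusted p = 0.00890, and adjusted p = 0.371 with an estimated correlation). NF-kB-responsive genes were higher (28 of 33 higher, list adjusted p = 9.41e-39, and adjusted p = 0.00189 with an estimated correlation). So were interferon-responsive genes (28 of 37 higher, 1 lower, adjusted p = 8.14e-24, and adjusted p = 0.111 with an estimated correlation). TLR pathway genes (10 of 24 higher, 1 lower, adjusted p = 6.23e-06, and adjusted p = 0.0575 with an estimated correlation) and glycolysis genes (8 of 20 higher, 1 lower, adjusted p = 0.000321, and adjusted p = 0.0575 with an estimated correlation) were higher. NRF2-responsive genes (4 of 15 higher, 2 lower, adjusted p = 0.0104, and adjusted p = 0.371 with an estimated correlation) lost their call without FA+LPS replicate 2 (adjusted p = 0.131). Lysosomal genes were lower (9 of 21 lower, 2 higher, adjusted p = 0.00579, and adjusted p = 0.129 with an estimated correlation).

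In all, 2376 genes changed between FA+LPS and unstimulated cells, 981 higher and 1395 lower, 648 of them at least 2-fold. With slide as a block all 25 named genes past the threshold stayed past it. Cell type markers had 5 of 12 higher and 3 lower for macrophages (adjusted p = 0.167), 2 of 8 higher and 1 lower for neutrophils (adjusted p = 0.272), 1 of 8 higher for dendritic cells (adjusted p = 0.203) and 1 of 10 higher for mesothelium and fibroblasts (adjusted p = 0.639). Of 2 T and NK cell markers 1, Il7r, was lower, and no B cell, eosinophil or mast cell marker was called by limma. With median scaling, 764 genes were called, 64.5% of them higher against 41.3%. Lipa (adjusted p = 0.157), Acaa1a (0.0730), Slc25a20 (0.188) and the lysosomal list (0.0804) were then not called.

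The interaction asked whether the fatty acid effect differed with LPS from that without it. Scd1 was the clearest such gene: its fatty acid effect was -1.88 without LPS and -0.06 with it, a difference of 1.82 ± 0.19 (adjusted p = 0.00173). Its mean log2 signal was 8.51 in unstimulated cells, 6.63 with FA, 6.65 with LPS and 6.59 with both, and on the dimmest of the last 12 arrays it lay 0.21 above background. Aqp9 (-1.52 ± 0.21, adjusted p = 0.0197), Hsd17b4 (0.62 ± 0.10, adjusted p = 0.0436), Ptx3, which encodes a pentraxin (-1.10 ± 0.17, adjusted p = 0.0436), the ectoenzyme Bst1 (0.93 ± 0.15, adjusted p = 0.0436) and the betaine transporter Slc6a12 (1.22 ± 0.20, adjusted p = 0.0498) also passed. The stress response list had a negative interaction, with a mean of -0.44 and 4 of 19 members below 0 when adjusted over the list alone (list adjusted p = 2.15e-07, and adjusted p = 0.00428 with an estimated correlation). Interferon-responsive genes had a mean of -0.51 (list adjusted p = 7.35e-07, and adjusted p = 0.356 with an estimated correlation). Positive list interactions were those of sterol synthesis (0.56; adjusted p = 5.75e-12), fatty acid synthesis (0.39; adjusted p = 3.81e-06), fatty acid oxidation (0.15; adjusted p = 0.00282), the LXR-responsive genes (0.21; adjusted p = 0.0420), the respiratory chain (0.14; adjusted p = 0.00328) and the tricarboxylic acid cycle (0.17; adjusted p = 0.00976). With an estimated correlation these had adjusted p = 0.170 for the sterol, fatty acid synthesis, oxidation and LXR lists and adjusted p = 0.190 for the respiratory chain and tricarboxylic acid cycle lists. The tricarboxylic acid cycle call was lost without LPS replicate 3 (adjusted p = 0.0927) or FA+LPS replicate 2 (adjusted p = 0.0555). The LXR call was lost without any of FA replicates 1 and 4, LPS replicates 2, 3 and 4, FA+LPS replicates 1 and 3 and unstimulated replicates 3 and 4 (adjusted p from 0.0508 to 0.146).

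Altogether 6 genes had an interaction, 4 positive and 2 negative, and 632 had an unadjusted p below 0.05, where chance gives 649. A replicate block called 20 genes, all 6 included, with Ddit3 (-2.04, adjusted p = 0.0470) and Trib3 (-1.51, adjusted p = 0.0463) among them. A slide block called Scd1 alone (1.84 ± 0.20, adjusted p = 0.00885). With it, Bst1 and Hsd17b4 had adjusted p = 0.0632, Ptx3 and Slc6a12 adjusted p = 0.0600 and Aqp9 adjusted p = 0.0551. The LXR-responsive list was no longer called (adjusted p = 0.124) and the fatty acid uptake list was (adjusted p = 0.0326, although without the block adjusted p = 0.201 with an estimated correlation). The stress response list had adjusted p = 0.0636 with a replicate block and an estimated correlation together. Median scaling called none by limma, with 237 genes at an unadjusted p below 0.05. Scd1 stayed called with each of the 15 arrays left out (highest adjusted p = 0.0131), Aqp9 with 10 of them (highest adjusted p = 0.115), Bst1 with 4 (0.166), Slc6a12 with 3 (0.166), Hsd17b4 with 2 (0.166) and Ptx3 with 2 (0.133).

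**Figure D4:**
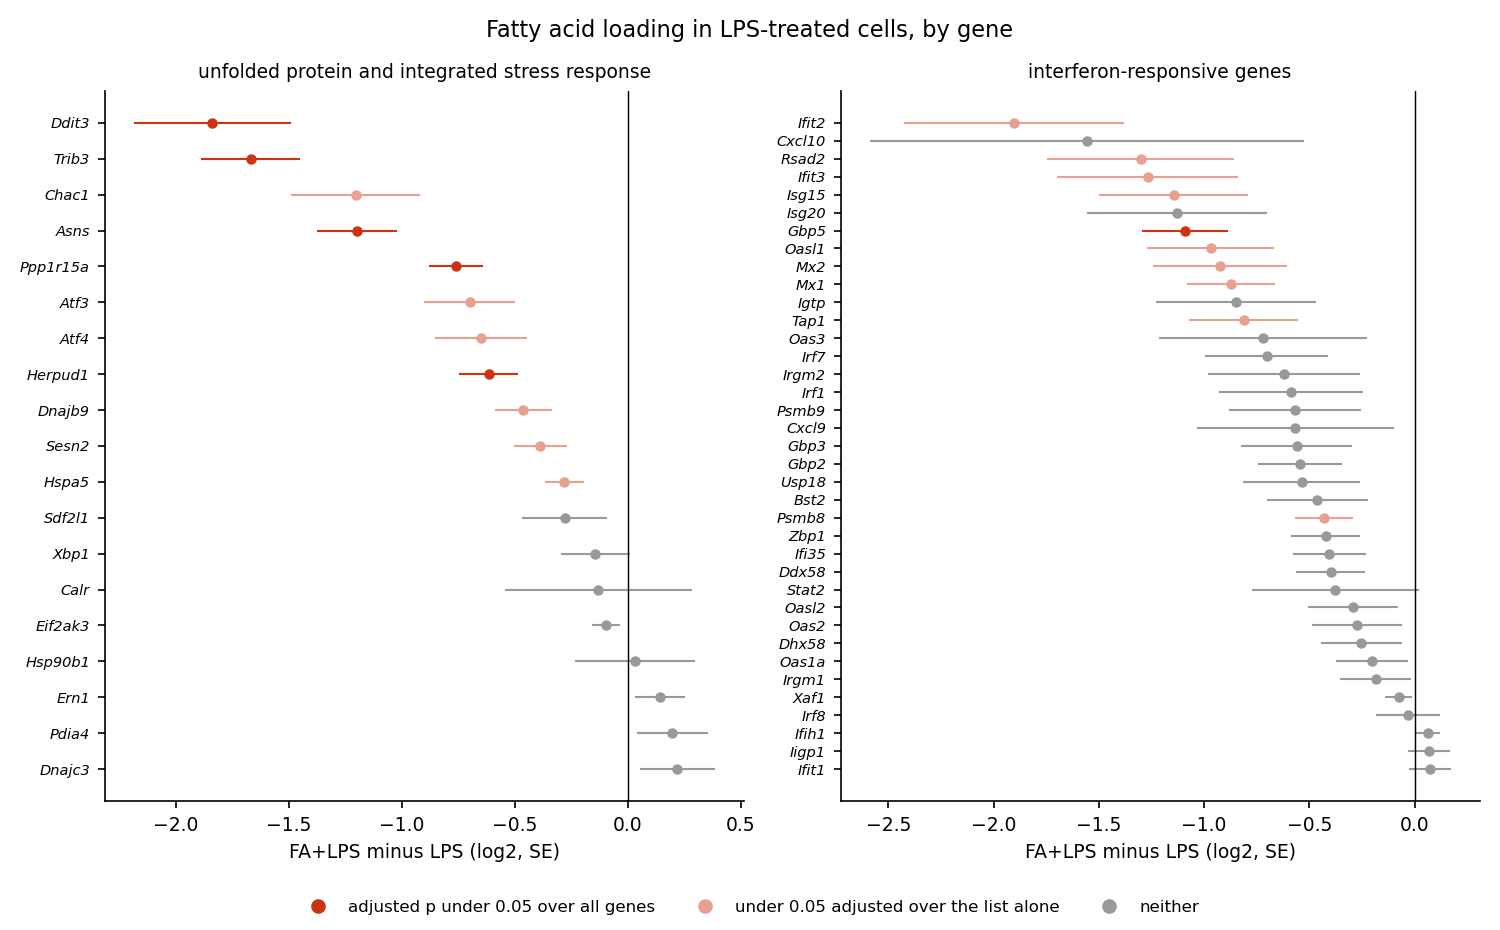
Log2 difference between FA+LPS and LPS (4 arrays each), with SE, of each member of the stress response list (left) and of the interferon-responsive list (right). Ddit3 lies at -1.84, Trib3 at -1.67 and Gbp5 at -1.09, and 34 of 37 interferon-responsive genes lie below 0.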

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

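The comparison of interferon-responsive with NF-kB-responsive genes and the Scd1 test without the dim array were chosen after the results were seen. Genes whose fatty acid effect differed with LPS from that without it, by the interaction term, were Scd1 (1.82), Aqp9 (-1.52), Slc6a12 (1.22), Ptx3 (-1.10), Bst1 (0.93) and Hsd17b4 (0.62). Lists called for such a difference at the preset correlation were sterol synthesis (mean 0.56), fatty acid synthesis (0.39), LXR-responsive genes (0.21), the tricarboxylic acid cycle (0.17), fatty acid oxidation (0.15), the respiratory chain (0.14), the stress response (-0.44) and interferon-responsive genes (-0.51). With an estimated correlation the stress response list stayed called (adjusted p = 0.00428), and the others had adjusted p from 0.170 to 0.356. Outside the named genes, 459 of 3906 retained probes with no gene name changed with LPS alone, 193 higher and 266 lower.

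Stress response genes were lower in FA+LPS than in LPS, with Ddit3 at -1.84 ± 0.35 and a list mean of -0.52. Its LPS and FA+LPS arrays shared a slide in each experiment, so differences between slides cancel by design and the medians within slides (at most -0.29) are no test of them. The tables argue against a single array, since the largest adjusted p over the 8 arrays left out in turn was 2.94e-10 and the mean closest to 0 was -0.46. By experiment the means were -0.64, -0.58, -0.62 and -0.24. An effect of the fatty acid on the stress response may underlie it, a hypothesis found and tested on the same arrays.

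Interferon-responsive genes had a list mean of -0.62 in FA+LPS against LPS, called at the preset correlation but with adjusted p = 0.166 with an estimated correlation. Of 37 members 1 passed, Gbp5 (-1.09 ± 0.20), and not without LPS replicate 3 or 4 or FA+LPS replicate 1, 2 or 3 (adjusted p from 0.0503 to 0.0727). The other probe of Gbp5 measured -0.20 and was not called. The highest list mean within an experiment was -0.44, which argues against a difference that rests on single experiments. A general weakening of the LPS response would lower NF-kB-responsive genes alike, but the interferon mean minus the NF-kB mean was -0.45 (SE 0.0965 across genes, which are not independent). A fatty acid effect on the interferon response may underlie the shift, and stays open.

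The fatty acid effect on Scd1, -1.88 ± 0.14 without LPS, measured -0.06 ± 0.13 with it. The dim array FA replicate 1 is not its source, since without that array the interaction was 1.82 with SE 0.20 and adjusted p = 0.00891. The signal of Scd1 lay as little as 0.21 log2 units over background in the 12 treated arrays, against at most 2.97 over all arrays. That floor could hide a further fall in LPS-treated cells, so a lost response and a floor cannot be told apart.

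Among 57 genes in groups of 4 arrays, 13 of 171 gene and group pairs held an array far from the other 3, where chance gives 8.55. These were FA replicate 3 for Adgre5 (gap over range 0.884), Cdkn1c (0.835), Daglb (0.870), Fpr2 (0.876) and Ptgs2 (0.830), FA replicate 1 for Dgat1 (0.834) and Il6 (0.853), and FA replicate 2 for Bst1 (0.837). In LPS arrays they were replicate 3 for Abcg1 (0.856), replicate 4 for Pdk4 (0.895) and replicate 1 for Ptgs2 (0.859), and FA+LPS replicate 4 stood apart for Cdkn1c (0.966) and Trib3 (0.882). No array stood apart in 12 tests of signal and background measures. These passed even FA replicate 1, whose 95th percentile of 7.77 lay below the 8.72 to 9.31 of the other FA arrays. They therefore do not show that the arrays were of even quality.

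Other splits of the arrays were fitted for each comparison, most of them across the experiments that pair the arrays. Only 8 splits per comparison of 2 groups part as many pairs as the real one, too few to exclude chance. For LPS against unstimulated cells (2892 genes, Il1b among them), 1 of 35 splits, the real one, gave as many, and the highest other gave 1117. The same held for FA+LPS against FA (2567, highest other 1) and FA+LPS against unstimulated cells (2376, highest other 920). For FA against unstimulated cells (1 gene, Scd1, highest other 1), 2 of 35 splits gave as many. A split that calls any 1 gene ties this count, so it does not address Scd1 itself (limma adjusted p = 2.16e-05). The split that tied set experiments 3 and 4 apart, and the highest other among the 8 splits that part all 3 pairs gave 0. For FA+LPS against LPS 4 of 35 splits gave at least as many (89, highest other 387), so chance is not excluded. For the interaction 7 of 100 drawn splits did (6, highest other 16). Those draws ignored the pairing, so chance is not excluded there either. In FA+LPS against LPS, the split of experiments 1 and 2 from 3 and 4 gave 387 and that of 1 and 4 from 2 and 3 gave 101, which points to a structure of the arrays by experiment. Among the 8 splits that part all 4 pairs, the highest other gave 0, and with a replicate block the real comparison gave 344.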

How the results depend on the processing

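The background correction with unretained probes as negative controls and the replicate block with an estimated correlation were chosen after the data were seen. Il1b, Tnf, Cdkn1c, Mgll and Daglb kept their LPS calls in every alternative run, and Scd1 its call for FA against unstimulated cells. FA+LPS against LPS (89 genes) gave 344 with a replicate block, 228 with a random one, 166 with a slide block, 481 with both blocks, 6 with median scaling, 12 with only the groups compared, 32 without experiment 2 and 25 at 2-fold. The interaction (6) gave 20, 10, 1 and 45 with those 4 blocks, 0 with median scaling (237 unadjusted by limma), 10 with trend and robust moderation, 11 with array weights, 1 without experiment 2 and 1 with negative controls. FA against unstimulated cells gave 3 with a replicate block. Median scaling gave 927 for LPS against unstimulated cells, 925 for FA+LPS against FA, 764 for FA+LPS against unstimulated cells and 637 shared LPS genes; at 2-fold these comparisons gave 789, 655 and 648. Testing every probe gave 3932 for FA+LPS against FA and 3585 for FA+LPS against unstimulated cells, as more features are tested. List shifts (49) numbered 18 with an estimated correlation and 17 with that and a replicate block. Single arrays left out gave 1 to 2, 2285 to 2987, 2275 to 2705, 57 to 186, 1827 to 2513 and 1 to 19 genes in the order FA, LPS, FA+LPS against FA, against LPS, against unstimulated, interaction. They gave 48 to 54 list shifts, 1774 to 2050 shared LPS genes and 0 to 0 shared fatty acid genes. The interaction count was 19 without FA+LPS replicate 4, 12 without LPS replicate 3 and 1 to 3 without any other array. Reversed were, in FA+LPS against FA with median scaling, Bscl2 (0.21) and the lysosomal list (0.0276). The NRF2 list, uncalled before, ranged with arrays left out from -0.11 to 0.11 in FA+LPS against LPS and from -0.12 to 0.10 in the interaction, the negative ends without FA+LPS replicate 2, where it was called (adjusted p = 0.0258 and 0.0385). Of 10729 gene values, the reversed one included, 10028 counted as unchanged, 321 moved, 332 lost and 47 gained a call. Unchanged meant the same direction and call, except for differences within slides, which have no test. Those counted as unchanged where they lay no further from the main value than the SD within groups. Within slides 1, 2 and 3, 199, 107 and 192 values were unchanged and 112, 20 and 119 moved. Of 4974 list values, the 3 reversed ones included, 4592 kept direction and call, 168 moved, 111 lost and 100 gained a call. The replicate block changed no call of a gene or preset-correlation list beyond those given with their comparisons and Arg1 with LPS (1.46, adjusted p = 0.00493). Except where stated, the cause was not tested. Signal over background limits dim genes such as Dgat2 and Scd1.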

Other observations

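The tests of the ATF4 and chaperone lists were written after the stress response list was seen and before those lists were tested. The genes named in the rest of this paragraph were chosen after their values were seen. Mfge8, which encodes a bridge to phosphatidylserine on dying cells, fell by 2.12 ± 0.14 with LPS against unstimulated cells, and the TAM receptor ligands Gas6 and Pros1 measured -1.91 ± 0.12 and -1.92 ± 0.16. The TAM receptor gene Axl went the other way and rose by 3.38 (limma adjusted p = 6.14e-06), while its other probe measured 0.16 and was not called. In prostaglandin synthesis, Ptges, for prostaglandin E synthase, rose by 4.05 ± 0.26 and Hpgds, for prostaglandin D synthase, fell by 1.96 ± 0.17. The arginine transporter Slc7a2 rose by 5.07 ± 0.27 (33.6-fold) and Ass1, which rebuilds arginine from citrulline, by 2.65 ± 0.33. In cholesterol handling, the ester hydrolase Nceh1 fell by 2.72 ± 0.15 and the sterol hydroxylase Cyp27a1 (-2.25 ± 0.10) was lower, while Ch25h, for cholesterol 25-hydroxylase, rose by 2.53 ± 0.54. In loaded cells LPS moved these genes likewise, with Slc7a2 at 5.42 ± 0.25, Ptges at 4.65 ± 0.24, Nceh1 at -2.49 ± 0.14 and Mfge8 at -2.08 ± 0.13.

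A further hypothesis asked which arm of the stress response is lower in FA+LPS than in LPS. Of 27 ATF4 target genes outside the fixed list, among them genes of amino acid synthesis, transport and tRNA charging and regulators such as Atf5, all 27 were lower, 5 of them called (mean -0.35, p = 1.25e-05 with an estimated correlation). Gtpbp2, chosen after its value was seen and not in that list, measured -1.34 ± 0.15, and the list members Mthfd2 and Aars measured -0.89 ± 0.10 and -0.80 ± 0.10. Of 21 chaperone and secretion genes outside the fixed list, none was called and 11 were lower (mean -0.0564). This argues against a change of these 21 genes of the size seen for ATF4 targets. It does not cover the chaperone genes of the fixed list, such as Hspa5, Pdia4 and Herpud1. Of those, Herpud1 was called lower (-0.62, limma adjusted p = 0.0448) and none was called higher. Without LPS the ATF4 list had a smaller mean of the same sign (-0.09, 20 of 27 lower, limma camera with an estimated correlation p = 0.0405), and its interaction mean was -0.26 (limma camera p = 0.000264). Fatty acid loading may thus bear on the ATF4 arm, more so in LPS-treated cells, which protein or amino acid measurements could test. The ATF4 and chaperone lists were tested only in the main fit and in none of the alternatives. Their p-values are not adjusted over lists or comparisons.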
